A study of Mus musculus with 30 samples.

How the data were processed

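The study holds 30 samples, of which 14 are bulk RNA-seq, 12 single-cell RNA-seq and 4 whole-genome bisulfite libraries of mouse cells. Each group has 1 library per the labels. The values used here are the deposited FPKM values of the 14 bulk libraries (fragments scaled to gene length and library size, made by the authors and named as FPKM in the sample descriptions). Per the labels, bulk RNA was total RNA and libraries were made with the NEBNext Ultra RNA kit. The submitters' processing notes give the mouse build mm10 and name FastQC, Cell Ranger 2.0.1, Bismark and Bowtie2, without saying which was used for the bulk RNA-seq. The aligner, counting tool, gene annotation and strandedness behind the FPKM values are not given in the sources used here. The single-cell and bisulfite data were not analysed here, because their values are not given in the sources used here.

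Per the labels, MEFs came from E13.5 embryos, cells were replated at day 12, stage II began at day 16 and stage III at day 28, and XEN-like lines were kept with 20 ng/ml bFGF. Most libraries came from a cross of a C57BL/6J reporter strain with ICR, the ESC line from ICR, and the Zscan4c reporter pair from a cross of 129S6/SvEvTac with C57BL/6Ncr, so the reporter pair and the ESC line differ in strain from the others. The table had 35275 entries under 35203 distinct names. Of the entries, 31136 matched the reference table of gene names and 26867 the RefSeq table by symbol. Another 126 entries shared a name, and a list used the entry with the highest mean. A date stood in place of the name in 27 entries, which held at most 0.234% of a library's FPKM; they stayed in totals and counts and were not named.

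Because FPKM of an entry differs between libraries only by its reads and the library total, the ratios of values across entries gave the ratio of totals, and the smallest whole numbers in the right ratios gave the reads. The total of the first library was set so that gene lengths came out whole, and they were whole within 0.001 base for 99.98% of 18186 entries checked. Reads were recovered for all 23178 entries above 0 in at least 2 libraries; 2231 were above 0 in 1 library only and 9866 were at 0 throughout. Recovered totals were 6601290 to 15294927 reads. From these reads, exact 95% binomial counting intervals were computed for ratios between libraries. A ratio against 0 reads is given as at least N-fold, computed against a floor of 3 reads in that library. It carries no interval, and it can lie above the lower limit of a two-sided interval for the same ratio. The fold itself is the ratio of the deposited FPKM values, without a pseudocount.

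Each of 11 comparisons set 1 library against 1 library, so no test was run. Log2 folds used log2(FPKM+1), and a gene was counted as higher or lower at a 2-fold difference on that scale among genes at 1 FPKM or more in either library. Counting error was simulated 20 times per comparison by drawing both libraries from their pooled proportions. The 27 gene lists (533 entries) covered fibroblast, epithelial, extraembryonic endoderm, visceral endoderm products, 2-cell-like, naive pluripotency, primed or formative pluripotency, trophoblast, germline, DNA methylation machinery, histone deacetylases, proliferation, p53 targets, immediate early, imprinted, Hox, retinoic acid targets, Wnt targets, cholesterol synthesis, glycolysis, interferon response, endothelial, immune, neural, muscle, mitochondrially encoded, and X and Y linked sex genes. The median log2 fold of a list with at least 3 measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins, and called when its percentile lay outside 2.5 to 97.5. Genes are not independent, so the percentile is a description. Similarity to ESC and MEF was the Spearman and Pearson correlation over genes at 1 FPKM or more in any bulk library. The 100 genes with the largest rise in the reporter pair were followed in the 3 comparisons named in the report.

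The lists, comparisons and the rule for naming genes were set before the data were examined. A gene is named in a comparison if it is 1 of 26 key genes at 1 FPKM or more in either library, or among the 3 members of a list with the largest fold of at least 2, or among the 5 largest rises and 5 largest falls of all genes at 10 FPKM or more. The last part leaves out symbols of the Gm, Rik, LOC, Mir, Snor, Rn and mt- forms, expressed-sequence names that start with AA, AI, AW, BC or C, shared names and dates. Largest rise and fall in the report mean within this set.

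The method was tested on simulated data, with known folds put into reads drawn at the depths of stage II N2B27 against XEN-like cells over 13409 genes. It called 0 of 50 genes at 1.5-fold, 16 of 50 at 2-fold, 50 of 50 at 4-fold, 50 of 50 at 8-fold, and 57 of 13209 unchanged genes (0.432%). Of 200 unchanged lists of 25 genes, 12 lay outside the central 95%. Reads were recovered exactly for 1425 of 1448 simulated genes (98.4%).

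Alternatives tried were a pseudocount of 0.1, no filter on low values, a filter at 5 FPKM, median-of-ratios scaling over 9302 genes, each library scaled to the same sum, the entries of a symbol summed, 50 or 200 reporter genes, the reporter genes without the 2-cell-like list, and the FBS/KSR library as the base for the sorted OG+ cells. Chosen after seeing the data were the FBS/KSR base for stage III day 6 and the removal of mitochondrially encoded genes, ribosomal protein pseudogenes and the genes that move with Slc38a6. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.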

Results

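Chemical reprogramming turns mouse embryonic fibroblasts (MEFs) into pluripotent cells with small molecules alone, by way of cells that resemble extraembryonic endoderm stem cells (XEN-like cells). The data collected were 30 samples in 30 groups, 1 library each. Of these, 12 were single-cell RNA-seq libraries, 14 were bulk RNA-seq libraries and 4 were whole-genome bisulfite libraries. The values below are those of the 14 bulk libraries. The single-cell and bisulfite libraries were not analysed here. A first set of libraries followed the process in order, from MEF and XEN-like cells through stage II day 12 (N2B27 medium) and stage III days 6, 15 and 21 to a chemically induced pluripotent stem cell (CiPSC) line, with an embryonic stem cell (ESC) line as the reference. The other libraries were arms at single time points. These were stage II day 12 cells made in a medium with serum and serum replacement (FBS/KSR), stage II day 12 cells sorted as OG+ PDGFRAlow/- PECAM-, stage III day 4 cells with and without Opt. VPA (valproic acid, a histone deacetylase inhibitor), and stage II day 12 cells sorted as positive or negative for a Zscan4c reporter. The reporter pair started from XEN-like cells derived from reporter ESCs of another strain.

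The depth recovered from the FPKM values ran from 6601290 reads in the stage III day 4 control to 15294927 in the FBS/KSR library. The MEF library held 9774904 reads, the XEN-like library 8475843 and the stage II N2B27 library 7538760. Stage III days 6, 15 and 21 held 9533644, 7113624 and 8170803 reads in that order. The CiPSC library held 11494763 and the ESC library 9237860. The sorted OG+ library held 9430985, the Opt. VPA library 8411782, and the reporter-positive and reporter-negative libraries 7271325 and 8653274. Mitochondrially encoded genes took 14.1% of reads in the reporter-negative library and 7.37% in the reporter-positive library, against 1.25% in MEF to 4.67% in stage II N2B27 among the others. With 1 library per group, no difference below has a replicate check and no p-value is given. Counting error alone, simulated 20 times per comparison at the real depths, placed on average 33.8 to 66.8 genes at least 2-fold apart, and at most 86. The range given after a fold is its 95% counting interval. These intervals, and the floors of 3 reads behind "at least" folds against 0 reads, cover counting error only. For each gene list, the medians given lay outside the central 95% of matched random lists unless a percentile or another statement is given.

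Along the process, the lists of marker genes peaked in turn. Collagens and other fibroblast genes had their highest mean in MEF, genes of extraembryonic endoderm in XEN-like cells, and naive pluripotency genes at the end. Genes of the early 2-cell embryo appeared at stage II, were near absent by stage III day 21, and were present again in the pluripotent lines. As a mean of log2(FPKM+1) over its members, the fibroblast list stood at 8.14 in MEF, 3.60 in XEN-like cells and 1.23 in CiPSC. The extraembryonic endoderm list stood at 3.21, 7.92 and 2.08 in the same libraries. The 2-cell-like list stood at 0.02 in XEN-like cells, 3.07 at stage II, 0.20 at stage III day 21, 1.11 in CiPSC and 2.85 in ESC. For the naive pluripotency list the mean was 0.77 in MEF, 4.20 at stage II, 4.12, 5.72 and 6.43 at stage III days 6, 15 and 21, 6.56 in CiPSC and 6.81 in ESC. Trophoblast genes were highest at stage III day 6 within this series (5.25), interferon response genes at stage III day 15 (5.14) and germline genes at stage III day 21 (3.81). Across 16963 genes, the Spearman correlation with the ESC library was 0.728 for MEF, 0.816 for XEN-like cells, 0.840 for stage II N2B27, 0.795, 0.855 and 0.909 for stage III days 6, 15 and 21, and 0.971 for CiPSC. With the MEF library it was 0.838 for XEN-like cells and 0.734 for CiPSC. Pearson correlations with ESC ran from 0.750 for MEF to 0.978 for CiPSC. Genes are not independent replicates, so these are descriptions.

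**Figure D1:**
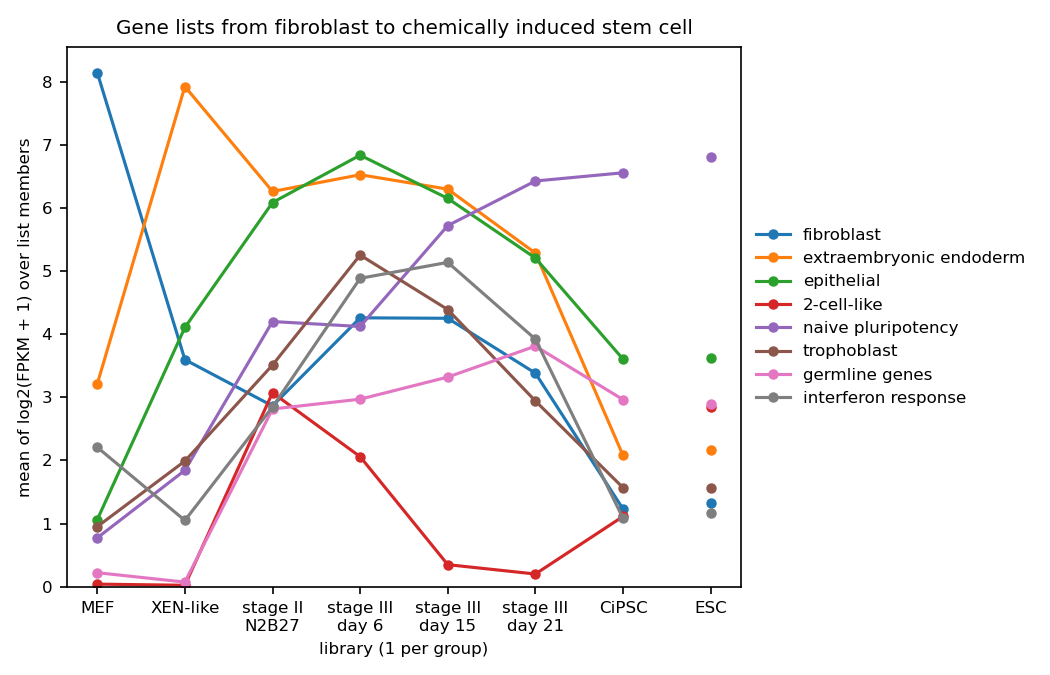
Mean of log2(FPKM+1) over the members of 8 gene lists (y axis) in the 7 libraries of the reprogramming series and the ESC library (x axis, 1 library each, ESC shown unconnected). The fibroblast list is highest in MEF (8.14), the extraembryonic endoderm list in XEN-like cells (7.92) and the 2-cell-like list at stage II (3.07).

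The first comparison asked how XEN-like cells differed from the fibroblasts they came from. XEN-like cells expressed the transcription factors that set up endoderm and the laminins and receptors of the yolk sac, and they had gained epithelial junction and keratin genes. They lacked most of the collagen matrix, the immediate early response genes and the muscle-type contractile genes of the MEF library. Of the extraembryonic endoderm list, 23 of 25 measured members were at least 2-fold higher and 0 lower (median log2 fold 4.26). Gata4, a zinc-finger factor of endoderm and heart, stood at 0.166 FPKM in MEF and 886 in XEN-like cells, 5350.0-fold (1830.3 to 25946) higher. Sox17, an endoderm factor of the Sox family, stood at 0.0441 and 405 FPKM, and Foxa2, a pioneer factor of endoderm, at 0.280 and 144. The water channel gene Aqp8 had 0 reads in MEF and 611 FPKM in XEN-like cells, at least 2636-fold higher. The fibroblast list had 0 of 30 measured members at least 2-fold higher and 28 lower (median log2 fold -4.54); Col1a1, which encodes the main collagen of connective tissue, was 498-fold (443 to 563) lower, from 9144 to 18.3 FPKM. Epithelial genes had 15 of 17 measured members at least 2-fold higher and 1 lower (median log2 fold 3.55), among them the adhesion molecule gene Epcam (0.201 FPKM in MEF and 138 in XEN-like cells) and the keratin gene Krt8 (5.10 and 621).

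Some genes of the naive pluripotency list were already expressed in XEN-like cells. Of its 28 members 15 were measured, with 11 higher and 1 lower (median 1.91). L1td1 and Tdh had 0 reads in MEF and 119 and 106 FPKM in XEN-like cells, whereas Klf2 stood at 37.8 and 0.256. In XEN-like cells Pou5f1 had 0 reads, and Nanog, Zfp42, Esrrb and Sox2 stood at 0.626, 1.05, 1.08 and 4.59 FPKM. Outside this list, Lin28a, which blocks maturation of let-7 microRNAs, had 0 reads in MEF and 226 FPKM in XEN-like cells. Sall4, a zinc-finger factor on the extraembryonic endoderm list, had 0 reads and 86.7 FPKM. The immediate early list had 0 higher and 15 lower of 16 (median -3.09), with the zinc-finger gene Egr1 at 233 and 0.251 FPKM. The muscle list had 0 higher and 10 lower of 10 (median -2.18) and the interferon response list 0 higher and 13 lower of 19 (median -1.40). Retinoic acid handling stood out in single genes, since Cyp26a1, whose product degrades retinoic acid, and Stra6, a retinol uptake receptor gene, had 0 reads in MEF and 715 and 581 FPKM in XEN-like cells, while the list of retinoic acid targets as a whole had 5 higher and 3 lower of 12 (median 0.56, at percentile 89.4 of the random lists). Histone deacetylase genes had 1 higher and 3 lower of 10 (median -0.27, at percentile 8.49 of the random lists), Hox genes 1 higher and 10 lower of 23 (median -0.54, at percentile 2.67 of the random lists) and the sex-linked genes 1 higher and 4 lower of 5 (median -1.39). At 5 FPKM or more, the interferon response and sex-linked medians lay inside the central 95%. The calcium-binding protein gene S100g was the largest rise over all genes (0.639 to 3403 FPKM), and Bgn, which encodes the matrix proteoglycan biglycan, the largest fall (2493 to 2.50). Over 13360 genes at 1 FPKM or more in either library, 2518 were at least 2-fold higher and 2341 lower. This split leaned on the scaling: median-of-ratios scaling moved the median of all genes by -0.29 log2 and gave 1754 higher and 2906 lower.

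The comparison of stage II day 12 in N2B27 medium with XEN-like cells asked how the cells differed before the medium for pluripotency. Stage II cells had more transcripts of the early 2-cell embryo and of a set of germline genes. They had more of part of the naive pluripotency set, with the octamer factor gene Pou5f1 but hardly any Nanog. Epithelial and interferon-stimulated genes were also higher, and part of the endoderm and cell cycle programmes was lower. Every measured member of the 2-cell-like list was at least 2-fold higher, 30 of 30 (median log2 fold 3.84). Zscan4c, Zscan4d and Zscan4f, zinc-finger genes of the 2-cell stage that act at telomeres, had 0 reads in XEN-like cells and 44.3, 48.5 and 103 FPKM at stage II, the last at least 447-fold higher. The Zscan4, Usp17l, Tdpoz and Tcstv genes are families of near-identical copies, so the level of a single member is uncertain wherever reads were shared among copies. Germline genes had 20 higher and 0 lower of 20 (median 2.84), with the piRNA-pathway gene Fkbp6 at 0 reads and 67.8 FPKM and Tex19.1, which restrains retrotransposons, at 0.110 and 57.3. Of the naive list, 18 of 24 members were higher and 1 lower (median 2.96). Pou5f1 had 0 reads in XEN-like cells and 149 FPKM at stage II (at least 312-fold higher), and Dppa5a, an RNA-binding protein gene of pluripotent cells, 0 reads and 1506 FPKM (at least 2634-fold). Esrrb, an orphan nuclear receptor gene of naive cells, was 89.5-fold (59.5 to 142) higher.

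Endoderm genes stayed expressed but lower, with 1 higher and 22 lower of 25 (median -1.57); Gata4 stood at 886 FPKM in XEN-like cells and 261 at stage II, and Sox17 at 405 and 135. The epithelial list had 15 higher and 0 lower of 20 (median 1.56), led by the tight junction gene Cldn4 (1.96 and 378 FPKM) and including the cadherin gene Cdh1 (17.7 and 344). Interferon response genes had 18 higher and 0 lower of 19 (median 2.42), with the ubiquitin-like gene Isg15 at 0.156 and 22.1 FPKM. Trophoblast genes had 10 higher and 3 lower of 18 (median 1.40), and Cdx2, the caudal-type factor of trophectoderm, stood at 0.574 and 43.2 FPKM. The proliferation list had 0 higher and 14 lower of 25 (median -1.02), the Hox list 0 higher and 11 lower of 20 (median -1.12), the neural list 0 higher and 7 lower of 10 (median -1.37) and the p53 target list 6 higher and 0 lower of 17 (median 0.77). Among all genes, Slc38a6, a member of the amino acid transporter family, took one of the highest values of the library, from 36.8 to 8101 FPKM (219.9-fold, 202 to 240.2), together with Ccrn4l, which encodes the deadenylase-like protein nocturnin (8.78 and 2062). Both moved closely with a set of other genes, so their levels are uncertain wherever reads were shared between loci. The intermediate filament gene Vim was among the largest falls (1052 and 36.4 FPKM). Over 13967 genes, 2474 were at least 2-fold higher and 1195 lower. N2B27 cultures were replated on mitomycin-treated MEF feeders, whose share of the reads is not given in the sources used here. The XEN-like cells were kept as lines with bFGF and the stage II library came from a timed culture, so culture and stage differ together.

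From stage II day 12 to stage III day 6, the comparison asked how the cells differed after entry into the last stage. Trophoblast, interferon response and fibroblast genes were higher. Against the N2B27 library the naive pluripotency set as a whole did not stand apart and Wnt target genes were lower; against the other stage II medium the naive set was slightly lower and the Wnt targets did not stand apart. Of the naive list, 4 of 27 measured members were at least 2-fold higher and 5 lower (median log2 fold -0.11, at percentile 33.3 of the random lists). Nanog, a homeobox gene of naive cells, stood at 0.576 FPKM at stage II and 8.96 at day 6 (15.6-fold, 8.01 to 34.6), whereas Esrrb was 6.65-fold (5.93 to 7.48) lower. Trophoblast genes had 13 higher and 1 lower of 19 (median 2.21): Gata3 and Elf5, factors of the trophoblast lineage, stood at 2.46 and 59.2 FPKM and at 2.79 and 49.2 FPKM. The largest rises over all genes were Prl7a1 and Prl2c5, placental hormones of the prolactin family, and Ctsll3, of the placental cathepsin family, all with 0 reads at stage II and 328, 178 and 247 FPKM at day 6. Members of both families are close copies of each other and single levels are uncertain. Interferon response genes had 22 higher and 0 lower of 24 (median 1.93), with Ifit3, which binds foreign RNA in a complex with its paralogs, at 0.152 and 18.8 FPKM. The fibroblast list had 18 higher and 3 lower of 30 (median 1.20), with Col3a1 at 3.23 and 189 FPKM. Wnt targets had 0 higher and 10 lower of 15 (median -1.59); the feedback inhibitor genes Axin2 and Notum stood at 59.1 and 7.28 FPKM and at 12.1 and 0.526 FPKM. The metallothionein gene Mt3 (69.5 and 0.195 FPKM) and the imprinted hydrolase-like gene Mest (223 and 8.97) were among the largest falls.

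The endoderm list had 7 higher and 2 lower of 25 (median 0.02, at percentile 79.1 of the random lists), and the DNA methylation genes 0 higher and 0 lower of 14 (median -0.31, at percentile 7.88 of the random lists). The 2-cell-like list had 0 higher and 21 lower of 31 (median -1.19), and Zscan4c stood at 44.3 and 16.3 FPKM. Over 14404 genes, 1439 were at least 2-fold higher and 1293 lower. The labels do not give the stage II medium behind the stage III libraries, and several of these directions depended on the base library. In the FBS/KSR library, Prl7a1 and Prl2c5 already stood at 177 and 72.6 FPKM, and Nanog, Esrrb, Axin2, Mt3 and Mest stood at 6.03, 35.4, 8.19, 0.122 and 5.68, nearer to their day 6 levels than in N2B27. Against that library, the naive median was -0.27, the Wnt target median -0.15, at percentile 9.01 of the random lists, the trophoblast and interferon response medians 0.76 and 0.85, and the extraembryonic endoderm median -0.82. The day 6 counts on that base were 839 higher and 279 lower, and the median of the 2-cell-like list was 0.14, at percentile 81.5 of the random lists, in place of -1.19. The medians of the p53 target and immediate early lists also changed sign, to 0.25 and -0.61 from -0.49 and 0.42.

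Between stage III days 6 and 15 the question was when the pluripotency network appeared. Most naive pluripotency genes were higher at day 15, including Nanog, Sox2 and the Akt cofactor gene Tcl1. The 2-cell-like genes had gone to near 0 and some trophoblast factors were lower. The naive list had 18 of 28 measured members at least 2-fold higher and 0 lower (median log2 fold 1.29). Nanog stood at 8.96 FPKM at day 6 and 143 at day 15, 16.0-fold (13.7 to 18.7) higher. Sox2, the partner factor of Pou5f1, stood at 8.41 and 119 FPKM (14.1-fold, 12.0 to 16.6), and Tcl1 at 2.44 and 84.8 (34.7-fold, 22.5 to 56.5). Pou5f1 itself was already expressed, at 138 and 216 FPKM. Otx2, a homeobox gene of the epiblast, stood at 0.269 and 17.9 FPKM, and the Nodal antagonist gene Lefty2 was among the largest rises of all genes (0.145 and 20.5). Of the DNA methylation machinery list, 4 of 14 were higher and 0 lower (median 0.41), with the 5-methylcytosine oxidase gene Tet1 at 2.05 and 24.1 FPKM and the imprint guardian gene Zfp57 at 30.8 and 208. The proliferation list had 5 higher and 0 lower of 25 (median 0.81). The 2-cell-like list had 0 higher and 23 lower of 25 (median -2.42); Zscan4f stood at 36.1 FPKM at day 6 and 1.09 at day 15, 33.0-fold (18.7 to 64.2) lower. Of the trophoblast genes, 0 of 18 were higher and 9 lower, with Cdx2 at 22.3 and 6.53 FPKM. Extraembryonic endoderm genes had 0 higher and 1 lower of 24 (median -0.27), and Gata4 and Sox17 stayed at 126 and 91.4 FPKM at day 15. Over 14247 genes, 888 were at least 2-fold higher and 715 lower.

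From stage III day 15 to day 21, most genes that differed were lower, and the endoderm, trophoblast, fibroblast and interferon response lists were among the lower ones. Pluripotency genes were higher again but mostly by less than 2-fold, and some glycolytic enzymes were higher. The naive list had 5 of 28 measured members at least 2-fold higher and 0 lower (median log2 fold 0.75), with the early embryonic chromatin gene Dppa2 at 15.0 and 40.3 FPKM and Nanog at 143 and 265. The extraembryonic endoderm list had 0 higher and 18 lower of 22 (median -1.09), and Sox17 was 3.19-fold (2.89 to 3.53) lower. Trophoblast genes had 0 higher and 12 lower of 18 (median -1.71); Hand1, a helix-loop-helix factor of giant cells, stood at 58.1 and 5.69 FPKM and the placental gene Plac1 at 56.9 and 5.25. Interferon response genes had 0 higher and 16 lower of 24 (median -1.28), with Irf7, the factor that amplifies interferon, at 145 and 37.1 FPKM. Glycolysis genes had 9 higher and 0 lower of 18 (median 0.99), among them Eno1 and Ldha, which encode enolase and lactate dehydrogenase, at 468 and 1379.8 FPKM and at 316 and 894 FPKM. Cholesterol synthesis genes had 1 higher and 0 lower of 21 (median 0.62). Germline genes had 4 higher and 0 lower of 22 (median 0.55), with the RNA-binding protein gene Dazl at 49.1 and 114 FPKM. Stra8, which starts meiosis, and Aire, a regulator of gene expression in thymic epithelium, were among the largest rises, at 8.62 and 40.8 FPKM and at 1.15 and 16.0 FPKM. Cdkn1c, an imprinted cell cycle inhibitor gene, stood at 115 and 12.9 FPKM, and 14 of 28 fibroblast genes were lower and 0 higher. Over 13744 genes, 236 were at least 2-fold higher and 1031 lower.

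The CiPSC line was set against stage III day 21 to ask what remained to be lost or gained once a line was established. Most genes of the endoderm, interferon response and fibroblast lists were lower in the line than in day 21 cells. Naive pluripotency genes were at much the same level, and 2-cell-like genes were present again. The naive list had 3 of 28 measured members at least 2-fold higher and 2 lower (median log2 fold 0.18, at percentile 73.4 of the random lists); Pou5f1 stood at 400.1 FPKM at day 21 and 756 in CiPSC, and Nanog at 265 and 364. The extraembryonic endoderm list had 0 higher and 20 lower of 22 (median -3.54), with Gata4 at 51.1 and 3.00 FPKM (17.0-fold lower, 13.2 to 22.3) and the basement membrane collagen gene Col4a1 at 824 and 11.1. Every measured interferon response gene was lower, 23 of 23 (median -2.67), and Isg15 stood at 56.3 FPKM at day 21 with 0 reads in CiPSC, at least 163-fold lower. Imprinted genes had 4 higher and 12 lower of 23 (median -1.28), with the growth factor gene Igf2 at 49.3 and 0.261 FPKM and the noncoding RNA H19 at 829.5 and 21.7. The DNA methylation list had 3 higher and 1 lower of 14 (median 0.19, at percentile 82.2 of the random lists); within it Dnmt3a, Dnmt3b and the cofactor gene Dnmt3l, which act in new DNA methylation, stood at 64.4, 48.2 and 211 FPKM in CiPSC against 11.5, 14.4 and 44.6 at day 21. Primed or formative genes had 5 higher and 1 lower of 13 (median 0.77), but at 5 FPKM or more their median was -0.10, inside the central 95% of random lists. Of the 2-cell-like list, 14 of 17 were higher and 0 lower (median 1.54), and Zscan4f stood at 0.159 and 19.4 FPKM. Retinoic acid targets had 2 higher and 7 lower of 12 (median -1.77), fibroblast genes 1 higher and 20 lower of 24 (median -2.32) and endothelial genes 0 higher and 6 lower of 8 (median -1.73); with no filter on low values, the retinoic acid target and endothelial medians lay inside the central 95%. Zg16, which encodes a lectin of secretory granules, stood at 437 FPKM at day 21 with 0 reads in CiPSC. The other largest falls were ribosomal protein pseudogenes such as Rps2-ps13 (589 and 0.493 FPKM), whose values are uncertain wherever reads were shared with their parent genes. Over 13486 genes, 658 were at least 2-fold higher and 2075 lower, with a shift of the median of all genes of 0.13 log2 under median-of-ratios scaling and -0.12 when each library was scaled to the same sum.

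Whether the chemically induced line matched embryo-derived stem cells was addressed by CiPSC against ESC. Naive pluripotency genes were close in both lines and a little lower in CiPSC as a list, while no difference stood out for epithelial or glycolytic genes. Among the lists given here, the 2-cell-like set differed most and was lower in CiPSC. Some imprinted genes were lower too. The strain labels differ between these lines, so strain and cell origin are not separable here. Of the naive list, 1 of 28 members was at least 2-fold higher and 1 lower (median log2 fold -0.31). The member that was higher was Utf1, a chromatin factor gene (131 FPKM in ESC and 289.6 in CiPSC), and the lower member was the naive-state factor gene Tfcp2l1 (103 and 47.8). Pou5f1 stood at 616 and 756 FPKM, Nanog at 518 and 364, and Zfp42 at 265 and 269. The 2-cell-like list had 0 of 30 measured members at least 2-fold higher and 28 lower (median log2 fold -2.19); Zscan4d stood at 51.4 and 7.52 FPKM (6.84-fold lower, 5.69 to 8.28) and the membrane protein gene Tmem92 at 27.4 and 3.01. Imprinted genes had 2 higher and 7 lower of 23 (median -0.47), with the adaptor gene Grb10 at 39.1 and 5.91 FPKM and the growth factor receptor gene Igf2r at 56.9 and 23.7. Within the DNA methylation list, Tet1 stood at 65.3 and 25.3 FPKM and Dnmt3l at 101 and 211. Glycolysis genes had 0 higher and 0 lower of 18 (median 0.22, at percentile 78.6 of the random lists) and epithelial genes 0 higher and 0 lower of 19 (median -0.02, at percentile 71.5 of the random lists). Over 12821 genes, 230 were at least 2-fold higher and 611 lower. Median-of-ratios scaling moved the median of all genes by 0.10 log2 and gave 307 higher and 461 lower, and scaling each library to the same sum moved it by -0.12 and gave 231 higher and 1024 lower.

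The media arm compared N2B27 with FBS/KSR at stage II day 12, to ask how intermediate cells kept in different media differed. In N2B27 the cells had more of the 2-cell-like and Wnt target transcripts and more Cdx2. In FBS/KSR they had more visceral endoderm products, trophoblast and interferon response transcripts, and more Nanog. The 2-cell-like list had 19 of 30 measured members at least 2-fold higher and 0 lower (median log2 fold 1.32), and Zscan4c stood at 13.1 FPKM in FBS/KSR and 44.3 in N2B27 (3.39-fold higher, 3.01 to 3.81). Wnt targets had 12 higher and 1 lower of 15 (median 1.82): Axin2 stood at 8.19 and 59.1 FPKM, the Wnt-dependent factor gene Sp5 at 0.249 and 9.85, and Cdx2 at 3.38 and 43.2. Visceral endoderm products had 0 higher and 11 lower of 14 (median -2.06), with the thyroxine carrier gene Ttr at 11.2 and 0.218 FPKM and the endocytic receptor gene Cubn at 127 and 4.48. Trophoblast genes had 2 higher and 10 lower of 20 (median -1.07), and the placental lactogen gene Prl3d1 stood at 41.1 and 0.312 FPKM. Prl7a1 and Prl2c5 had 177 and 72.6 FPKM in FBS/KSR and 0 reads in N2B27. Interferon response genes had 0 higher and 13 lower of 24 (median -1.06). Of the naive genes, 3 of 26 were higher and 5 lower (median -0.23, inside the central 95% under some alternative settings); Nanog stood at 6.03 FPKM in FBS/KSR and 0.576 in N2B27, and Esrrb at 35.4 and 96.9. The p53 target list had 6 higher and 0 lower of 17 (median 0.74) and the retinoic acid target list 5 higher and 2 lower of 14 (median 0.67). The largest rise over all genes was Cma2, a mast cell protease gene (0.345 and 84.9 FPKM). Over 14047 genes, 1507 were at least 2-fold higher in N2B27 and 1025 lower. Feeders are described in the labels for the N2B27 condition only at this stage, so medium and feeders differ together.

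The sorted reporter pair asked which genes go with Zscan4c activity among stage II cells. Reporter-positive cells had the whole 2-cell-like set and some germline genes at higher levels. Some genes of the epithelial, extraembryonic endoderm, trophoblast and Wnt target lists were lower in them. All 32 measured members of the 2-cell-like list were at least 2-fold higher (median log2 fold 4.39). Zscan4c itself, whose promoter drives the reporter, stood at 32.5 FPKM in reporter-negative and 1172 in reporter-positive cells, 36.1-fold (33.4 to 39.1) higher, which is what the labels of the pair require. Zscan4f stood at 83.9 and 2759 FPKM and the 2-cell gene Tcstv3 at 2.95 and 184. The level of these genes in reporter-negative cells was 3.20% of that in reporter-positive cells at the median over 32 genes, and 20.3% at the highest. The naive list had 5 higher and 2 lower of 22 (median 0.60), with Dppa2 at 10.4 and 76.0 FPKM and Pou5f1 at 70.4 and 134. Germline genes had 7 higher and 0 lower of 20 (median 0.87), and the piRNA-pathway gene Mael stood at 1.94 and 12.7 FPKM. Epithelial genes had 0 higher and 9 lower of 20 (median -0.81), with Krt19 at 153 and 55.3 FPKM, and Wnt targets had 0 higher and 6 lower of 15 (median -0.81). The extraembryonic endoderm list had 0 higher and 6 lower of 25 (median -0.57) and the trophoblast list 0 higher and 5 lower of 16 (median -0.76). Sox17 stood at 222 and 106 FPKM and Lin28a at 74.7 and 24.3. The mitochondrially encoded list had 0 higher and 4 lower of 12 (median -0.75). The orphan nuclear receptor gene Nr4a1 was among the largest falls (36.7 and 4.95 FPKM). Over 13413 genes, 1123 were at least 2-fold higher and 691 lower. This split leaned on the scaling, with 1118 higher and 983 lower when each library was scaled to the same sum. It was 1059 and 960 without mitochondrially encoded genes, ribosomal protein pseudogenes and the genes that move with Slc38a6. Under median-of-ratios scaling it was 1294 and 658.

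The 100 genes with the largest rise in reporter-positive cells were then followed in pairs that share no library with the reporter pair. They were higher with N2B27 than with FBS/KSR, with 61 of 91 measured genes at least 2-fold higher and 0 lower (median log2 fold 1.35). They were also higher with Opt. VPA than in the control, with 68 higher and 0 lower of 74 (median 2.01). In CiPSC against ESC, 0 were higher and 76 lower of 83 (median -2.12). The set held 25 members of the 2-cell-like list. With the list left out and the set refilled to the same size, the medians were 1.20, 1.86 and -1.75 in the same order, so genes beyond the list differed in the same direction.

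**Figure D2:**
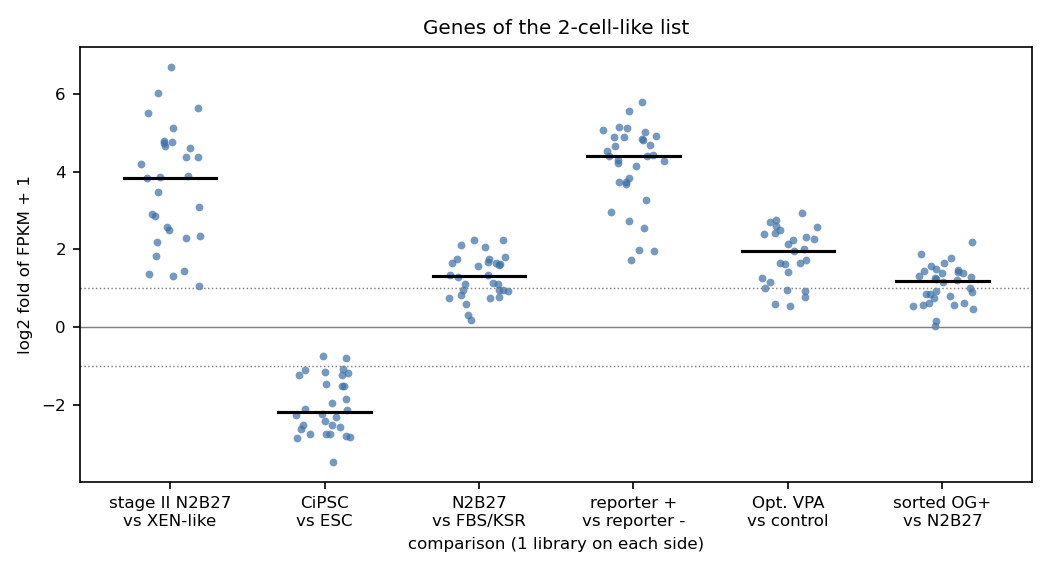
Log2 fold of FPKM+1 (y axis) of each measured gene of the 2-cell-like list (points) in 6 comparisons (x axis, 1 library on each side), with the median as a bar and dotted lines at a 2-fold difference. The medians are 3.84 for stage II N2B27 against XEN-like cells, -2.19 for CiPSC against ESC, 1.32 for N2B27 against FBS/KSR, 4.39 for the reporter pair, 1.95 for Opt. VPA against control and 1.18 for the sorted OG+ cells.

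The Opt. VPA arm asked how cells treated with valproic acid differed from control cells at stage III day 4. Most 2-cell-like genes and some cell cycle, germline and trophoblast genes were higher in treated cells than in the control, and the naive pluripotency set was slightly higher. Some visceral endoderm products were lower. The naive list had 2 of 23 measured members at least 2-fold higher and 1 lower (median log2 fold 0.47), with Utf1 at 0.988 FPKM in the control and 13.9 with treatment and Pou5f1 at 86.2 and 119.7, but Sox2 at 8.69 and 4.39 and Nr0b1 at 6.87 and 2.30. The 2-cell-like list had 22 higher and 0 lower of 27 (median 1.95), with Zscan4f at 8.25 and 69.3 FPKM (8.40-fold, 6.71 to 10.6) and Zscan4d at 2.33 and 18.0. Proliferation genes had 12 higher and 0 lower of 25 (median 0.96), among them Cdk1, the kinase gene that drives mitosis (23.7 and 64.0 FPKM), and Top2a, a topoisomerase gene of dividing cells (41.9 and 109). Trophoblast genes had 9 higher and 0 lower of 18 (median 1.05) and germline genes 7 higher and 0 lower of 16 (median 0.92). Dnmt3l stood at 10.1 and 34.4 FPKM and H19 at 641 and 3014. The histone deacetylase genes themselves had 0 higher and 0 lower of 10 (median 0.04, at percentile 30.9 of the random lists). Visceral endoderm products had 0 higher and 5 lower of 11 (median -0.87), with Ttr at 8.57 and 0.780 FPKM, and the extraembryonic endoderm list had 0 higher and 0 lower of 24 (median -0.55). The gap junction gene Gjb2 was the largest rise over all genes (0.944 and 48.0 FPKM). The pepsinogen gene Pga5 (328 and 16.0 FPKM) and the gastrokine genes Gkn1 (30.2 and 1.27) and Gkn2 (30.6 and 1.53) were the largest falls. Over 13571 genes, 783 were at least 2-fold higher and 445 lower, and median-of-ratios scaling moved the median of all genes by -0.11 log2 and gave 645 higher and 546 lower. With each library scaled to the same sum, 941 were higher and 679 lower. The lead of the naive list was small: with no filter on low values its median was 0.14, inside the central 95% of random lists.

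Cells sorted as OG+ PDGFRAlow/- PECAM- were compared with unsorted N2B27 cells of the same day, to ask how they differed. The libraries differ in the sorting itself too, and the MEF feeders of the N2B27 cultures may contribute to the unsorted library. Neither can be told apart here from traits of the sorted fraction, which also holds for the fibroblast genes. Genes of the trophoblast, epithelial, interferon response and 2-cell-like lists were higher in the sorted cells. Fibroblast, Wnt target and mitochondrially encoded transcripts were lower, the Wnt targets less clearly so against the other stage II medium. The 2-cell-like list had 18 of 32 measured members at least 2-fold higher and 0 lower (median log2 fold 1.18), with Zscan4f at 103 FPKM unsorted and 382 sorted. Pdgfra, the surface receptor the sort selected against, stood at 77.9 and 17.8 FPKM (4.37-fold lower, 4.08 to 4.67). Trophoblast genes had 16 higher and 0 lower of 19 (median 2.32): Gata3 stood at 2.46 and 266 FPKM (108-fold, 67.3 to 186), the T-box gene Eomes at 3.99 and 90.5, and Cdx2 at 43.2 and 187. Epithelial genes had 12 higher and 0 lower of 20 (median 1.45), with Krt18 at 325 and 2349 FPKM. Naive pluripotency genes had 10 higher and 4 lower of 27 (median 0.65); Klf2 stood at 3.73 and 248 FPKM, Pou5f1 at 149 and 235, the germ cell gene Dppa3 at 18.8 and 89.1, and Esrrb at 96.9 and 30.1. Interferon response genes had 20 higher and 0 lower of 23 (median 2.03) and immune markers 5 higher and 2 lower of 11 (median 0.36, at percentile 90.9 of the random lists). Fibroblast genes had 1 higher and 19 lower of 28 (median -1.30), with the matrix protease gene Mmp2 at 81.2 and 1.61 FPKM. Wnt targets had 2 higher and 11 lower of 15 (median -1.95), mitochondrially encoded genes 0 higher and 8 lower of 12 (median -1.10) and proliferation genes 0 higher and 11 lower of 25 (median -0.87). The early response gene Fosb (0.849 and 131 FPKM) was among the largest rises, and the retinoid-binding protein gene Crabp1 (310.0 and 0.264) among the largest falls. Over 14348 genes, 1719 were at least 2-fold higher and 1722 lower. The labels do not give the medium of the sorted cells. The FBS/KSR library had Pou5f1 at 249.9 and Esrrb at 35.4 FPKM, near the levels in the sorted cells. Against the FBS/KSR library the median of the Wnt target list was -0.54 and that of the interferon response list 0.68. The median of the p53 target list changed sign, from -0.50 to 0.28, at percentile 90.3 of the random lists. Fibroblast genes had 0 higher and 18 lower of 26 on that base (median -1.69), and the labels describe no feeders for the FBS/KSR library.

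**Figure D3:**
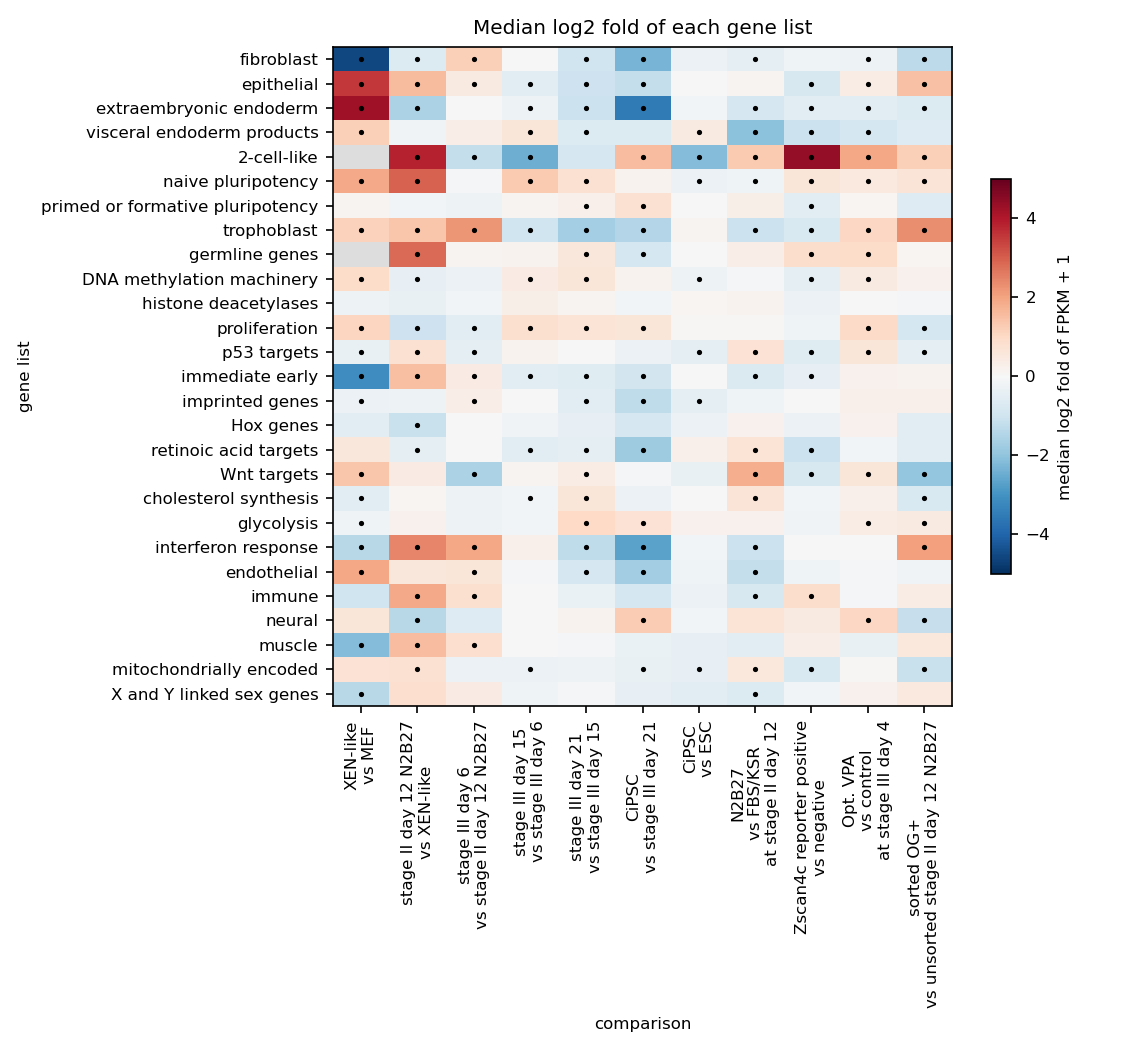
Median log2 fold of FPKM+1 (colour) of 27 gene lists (y axis) in 11 comparisons (x axis, 1 library on each side), with a dot where the median lay outside the central 95% of 10000 random lists matched on expression and grey where fewer than 3 members were measured. The 2-cell-like list is at 3.84 in stage II N2B27 against XEN-like cells and -2.19 in CiPSC against ESC.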

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

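The alternatives were fixed before the data were examined, except the FBS/KSR library as the base of the stage III day 6 comparison and the removal of 3 groups of entries (mitochondrially encoded genes, ribosomal protein pseudogenes and the genes that move with Slc38a6), which were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and leave-one-out could not be run for the same reason. The counts of genes at least 2-fold apart stayed within 1.5 times their reported value in 112 of 136 settings, among them all 22 counts under median-of-ratios scaling, with no filter on low values, and after removal of the 3 groups of entries. The count with no filter equals the reported one by construction, since a gene under 1 FPKM in both libraries cannot reach 2-fold at a pseudocount of 1. The median of the list that leads each comparison kept its side of the central 95% of random lists in 77 settings, moved outside it in 1 and inside it in 1. Direction was compared only for medians outside the central 95% at the settings of the report, and those among the 77 kept it. For the other lists, 1895 medians stayed by the same rule, 40 moved outside the central 95%, 55 moved inside it and 13 reversed. The 1895 include medians that changed sign inside the central 95%, such as glycolysis at stage III day 6 on the FBS/KSR base (-0.27 to 0.03). Summing the entries of a symbol accounts for 11 of the 77 and 282 of the 1895. That setting could change little, since only 1 list member, in the 2-cell-like list, has a shared name. Of the log2 folds of named genes, 2606 were counted as unmoved, judged by their counting interval, and 286 as moved. These counts are a rough guide only. The interval is that of the FPKM ratio without a pseudocount, whereas the log2 folds carry a pseudocount. A gene without reads in 1 library of a pair has no bounded interval, so its count as unmoved is no test. All 12 repeats of the reporter gene result kept their direction and side.

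With a pseudocount of 0.1 in place of 1, more genes passed 2-fold, as its construction requires, since low values weigh more. The counts were 1335 higher and 1187 lower for stage III day 15 against day 6, 507 and 1703 for day 21 against day 15, 455 and 1130 for CiPSC against ESC, and 1300 and 750 for Opt. VPA against control. They were 997 higher for CiPSC against stage III day 21 and 1191 lower for the reporter pair. With genes at 5 FPKM or more in either library, fewer genes were counted, which lowers the counts by construction. They were 590 higher and 414 lower for stage III day 15 against day 6 and 453 higher and 274 lower for Opt. VPA against control. The number higher was 1518 for stage II N2B27 against XEN-like cells, 139 for stage III day 21 against day 15, 429 for CiPSC against day 21, 141 for CiPSC against ESC and 714 for the reporter pair, and the number lower was 1137 for the sorted OG+ cells. Scaling each library to the same sum gave 1024 lower for CiPSC against ESC and 679 lower for Opt. VPA against control; the cause was not tested.

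Some list medians that lay outside the central 95% at the settings of the report changed sign or went to 0, and the cause was not tested. At 5 FPKM or more, reversed medians, each with its value at the settings of the report in parentheses, were -0.054 for the endothelial list and -0.19 for the muscle list at stage III day 6 (0.61 and 0.84), -0.10 for primed or formative genes in CiPSC against stage III day 21 (0.77) and -0.24 for immune genes in the reporter pair (0.87). With no filter they were 0 for those immune genes, 0 for visceral endoderm products in CiPSC against ESC (0.46) and -0.13 for visceral endoderm products at stage III day 15 against day 6 (0.60). That last median was -0.18 with each library scaled to the same sum. The naive list of the Opt. VPA pair, reported at 0.47, was at 0.14 with no filter, inside the central 95%. With the FBS/KSR library as the base, the p53 target median of the sorted OG+ cells was 0.28.

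For stage III day 6, that base gave 839 genes higher and 279 lower in place of 1439 and 1293. Of the medians outside the central 95% on the N2B27 base, those that reversed were 0.14 for the 2-cell-like list, 0.25 for p53 targets, -0.61 for immediate early genes and -0.60 for endothelial genes. Some medians inside it also changed sign. Among these were extraembryonic endoderm (0.02 to -0.82), visceral endoderm products (0.32 to -1.25) and cholesterol synthesis (-0.25 to 0.21). The naive list moved from -0.11 to -0.27, outside the central 95%. Which library is the right base is not given in the sources used here.

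Correlations moved with the filter on low values and, for Pearson, with the pseudocount; Spearman is unaffected by a pseudocount by construction. The values follow in a fixed order, leaving out the reference itself: MEF, XEN-like, stage II N2B27, FBS/KSR, sorted OG+, stage III day 4 control, Opt. VPA, stage III days 6, 15 and 21, CiPSC, ESC, reporter negative, reporter positive. At 5 FPKM or more, Spearman with ESC was 0.639, 0.769, 0.787, 0.758, 0.732, 0.667, 0.735, 0.722, 0.810, 0.895, 0.968, 0.778 and 0.758, and Spearman with MEF was 0.767, 0.689, 0.722, 0.619, 0.765, 0.775, 0.719, 0.722, 0.691, 0.648, 0.639, 0.673 and 0.608. Pearson with ESC was 0.649, 0.774, 0.798, 0.768, 0.745, 0.679, 0.745, 0.733, 0.815, 0.899, 0.972, 0.794 and 0.776 at that filter. It was 0.708, 0.798, 0.825, 0.812, 0.794, 0.743, 0.792, 0.780, 0.837, 0.894, 0.966, 0.826 and 0.806 with a pseudocount of 0.1. Pearson with MEF was 0.772, 0.691, 0.721, 0.613, 0.764, 0.773, 0.719, 0.725, 0.701, 0.660, 0.649, 0.680 and 0.612 at 5 FPKM or more. It was 0.831, 0.748, 0.773, 0.679, 0.811, 0.812, 0.765, 0.772, 0.751, 0.716, 0.708, 0.740 and 0.683 with the pseudocount of 0.1. Under each setting, CiPSC was the library closest to ESC.

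Depth limits the low end. With the recovered reads, counting error alone put up to 86 genes 2-fold apart in a comparison, and with 1 library per group the spread between cultures is unknown.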

Other observations

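All tests in this part were chosen after the results were seen, and the fibroblast and immune cell tests of the third pattern are not the first versions tried. The fibroblast test first counted interferon response genes above MEF, and the immune test first asked for an immune median under 20% of the interferon response median, which the N2B27 library would miss, at 1.01 against 4.86 FPKM, and then for the leukocyte gene Ptprc at no more than 1 read, which rested on a single gene near 0. Over all pairs of bulk libraries, the fewest genes at least 2-fold apart lay between CiPSC and ESC, 841 of 12821 (6.56%). The second closest pair was the FBS/KSR stage II library and stage III day 6, with 1118 of 13876 (8.06%). Opt. VPA and control came next with 1228, then stage III days 15 and 21 with 1267 and days 6 and 15 with 1603.

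The first pattern concerns ribosomal protein pseudogenes, of which 9 of 246 in the table were at 10 FPKM or more in some library and under 1 in another, such as Rps2-ps13 at 589 FPKM at stage III day 21 and 0.491 in ESC. Among the unsorted libraries the tables argue against the stage of reprogramming. Stage III day 4 differed from stage II day 12 and stage III day 6 by at least 2 of them, and those times by 0. The sorted OG+ library, also of stage II day 12, differed from N2B27 and from stage III day 6 by 3 each. With it counted, this comparison does not decide on stage. A setting that loses all of these entries in a library is argued against, since 28 of 91 pairs of libraries differed in both directions. A setting that divides reads among copies differently between libraries could give both directions and was not tested. A strain or donor variant against the reference, with reads shared between copies, may account for the pattern: the reporter pair, which has 1 source of cells, differed by 0, and the 35 pairs with different strain labels by at least 1. This test separates little, because 43 of 56 pairs with the same strain label differed too and the thresholds and the ribosomal set were chosen after a look at all 966 pseudogene entries, where 81 pairs differed. The Y-linked genes differed between libraries too. Eif2s3y stood at 1.79 and 4.39 FPKM in the stage III day 4 control and Opt. VPA libraries. In stage II N2B27 and at stage III day 6 it stood at 54.7 and 59.9. Ddx3y stood at 1.28 and 1.67 in the day 4 libraries against 9.01 and 23.3 at those times, and Xist at 58.4 and 44.8 against 38.5 and 61.9. The mix of donors behind each library was not tested, and the genotype of each culture stays open.

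The second pattern is a set of genes that moved with Slc38a6. These 7 genes (Gm14149, Gm10040, Gm9864, RP23-20G7.4, Rab3gap1, Ccrn4l and Wdr31) were chosen after their values were seen, by a Pearson correlation at the strictest of the minimums tried over 7 libraries, and with Slc38a6 they took 0.0157% of reads in XEN-like cells and 5.52% in the stage III day 4 control. The Slc38a6 ratio of stage II over XEN-like was 219.9 and the highest ratio of library totals 2.32. FPKM is already scaled to the library total, so this comparison could not test depth and no conclusion is drawn from it. Reads of 1 multi-copy transcript split between loci in a fixed proportion cannot be told apart from other causes: 34 of 35 combinations of gene and held-out library lay outside the counting interval, but that interval leaves out the spread between libraries. The median distance from the chosen ratio was 0.50 log2, against 2.44 for the other 258 candidates, but that minimum was set after held-out values were seen, so this tightness is partly selected; at a minimum of 0.98 it was 0.91 for 23 genes and at 0.99 it was 0.52 for 11. Shared reads and separate regulation could both give such a pattern and stay open.

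The third pattern is the interferon response, whose list had a median of 4.86 to 32.8 FPKM over the 8 stage II and III libraries outside the reporter pair, 2.81 in MEF and 0.445 in XEN-like cells, while the reporter pair stood at 1.62 (negative) and 1.56 (positive). Fibroblasts in the state of the MEF library, left in the culture, are argued against. The 30 fibroblast genes stood at a median of at most 8.22% of their MEF level in those 8 libraries. For feeder cells of the N2B27 condition, the median log2 fold of the interferon response list was -1.06 in N2B27 over FBS/KSR. The feeders described for N2B27 do not account for the higher level in FBS/KSR. Medium and feeders differ together, so this value cannot tell whether feeders were a source in N2B27 or in the other libraries. Immune cells cannot be told apart from the other cells as the source, since 4 of 15 immune genes reached the interferon response median in at least 1 of those libraries, while the median of the immune list was 0.324 to 2.02 FPKM and Ptprc reached 0.0462, or 1 read, at most. Among genes chosen after their values were seen, Cd68 and Laptm5 stood at 122 and 120.0 FPKM in the sorted OG+ cells, Csf1r at 0.402 in N2B27 and 11.6, 11.5 and 1.94 at stage III days 6, 15 and 21, and Laptm5 also at 127 in ESC. An interferon response of the reprogramming cells, immune cells, and fibroblasts or feeders that had themselves responded to interferon stay open. The tests above did not decide between them.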
